A study of Mus musculus with 6 samples.

How the data were processed

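RNA sequencing measured gene expression in 6 libraries of LPS-pretreated mouse macrophages, 3 from cells cultured for 24 h on MSA-ZW hydrogels and 3 from cells on MSA-DA hydrogels. Libraries were grouped by their titles, which also number them 1 to 3 in each group. Per the labels, libraries were made from total RNA extracted with Trizol. Whether messenger RNA was selected or ribosomal RNA depleted is not given in the sources used here.

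Per the submitters' processing notes, bcl2fastq 2.20.0.422, cutadapt 1.9.1 and HISAT2 2.2.1 were used with the genome build GRCm39. The counting tool, its strand setting and the annotation release are not given in the sources used here. The authors deposited 1 table of 56691 genes with raw counts and FPKM values for every library, per the file headers. The deposited counts are whole numbers. The FPKM values the authors deposited equal the count divided by exonic gene length and by the library's own count total, to within 0.011 for 100% of genes in each library. No row lacked a gene, and 33118 genes had no count in any library. Gene symbols and coordinates are those of the deposited table. Reads from paralogs, overlapping genes and antisense genes cannot be separated without the counting settings.

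Count totals were 16498956, 16347934 and 18193026 for MSA-ZW replicates 1, 2 and 3, and 14374912, 18346615 and 15812239 for MSA-DA replicates 1, 2 and 3. Between 18018 and 18691 genes had at least 1 count. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom of the counts was 1.56 to 1.65 within MSA-DA, 2.77 to 4.51 within MSA-ZW and 5.78 to 9.34 between groups. All 6 libraries were therefore used as separate samples. The first principal component of log2 CPM held 50% of the variance and separated the groups.

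The comparison of MSA-DA with MSA-ZW was tested with the edgeR 4.0.16 quasi-likelihood test on the deposited counts (TMM normalization, filterByExpr, glmQLFit, glmQLFTest, group as the only term) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05 over 12467 tested genes. The design allowed for limma on FPKM, or edgeR where counts were given; counts were given. Levels are CPM on TMM-scaled library sizes, and the standard error of a log2 difference is its size divided by the square root of the F statistic. The common biological coefficient of variation was 3.04%. The 2-fold count was set on the difference of mean log2(FPKM + 1), as fixed before the data were examined, and is given on the edgeR scale too. The log2(FPKM + 1) scale understates the change of low genes.

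Gene lists were tested with camera of limma 3.58.1 on log2(FPKM + 1), for genes with an FPKM of at least 1 in at least 3 libraries, with a preset correlation between genes of 0.01 and without a variance trend. The p-values were adjusted over the 27 lists with at least 5 such members. The 28 lists were written before the data were examined, as were the grouping, the tests and most alternatives. Lists of TGF-beta response and pathway genes, small nucleolar RNA host genes and nuclear-retained long noncoding RNAs were written after the calls had been seen. So were those of ribosomal-RNA-like loci and mitochondrial aminoacyl-tRNA synthetases. Gene-level counts use counts while the list test uses FPKM, so the genes each covers differ. Camera held 12 of the 15 tested inflammatory genes and 5 of the 10 tested nuclear-retained long noncoding RNAs.

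The rule for named genes was fixed before the data were examined. It took the 6 largest rises and 6 largest falls among called genes with a mean FPKM of at least 5 and groups that did not overlap, leaving out predicted genes, clones and mitochondrial genes. It always took Tnf, Il1b, Il6, Nos2, Arg1, Mrc1, Il10 and Tgfb1, and for each list past the threshold the 3 members with the smallest p in the list's direction. Genes named outside the rule were chosen after their values were seen. Values of 1 gene are not reported here.

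The fits were tested on simulated data for this comparison, drawn for 12467 genes from the real means and library sizes, with 50 genes changed at each fold. The edgeR fit recovered 48% of 1.2-fold, 68% of 1.5-fold, 78% of 2-fold and 94% of 3-fold changes, with 8 false calls. Among genes of at least 10 CPM it recovered 75% of 1.2-fold changes and 100% of the larger ones, so small changes in low genes were often missed. Fewer genes changed in the simulation than were called in the real data, and each gene had the same dispersion in both groups. The real MSA-ZW libraries agreed less than the MSA-DA libraries, so these shares need not hold for the real comparison.

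Alternatives fixed beforehand were DESeq2 1.42.0, no filter on low counts, limma on log2(FPKM + 1) with other pseudocounts, filters, scalings, variance models, library weights and a replicate block, leaving out each library in turn, an estimated correlation and fry for the lists. Alternatives added after seeing the data were RLE size factors, edgeR with a replicate block, edgeR without the ribosomal-RNA-like loci and mitochondrial genes, a GC content and length correction, a minimum fold of 1.2, the edgeR scale for the 2-fold count, and camera with a variance trend, on counts or after the GC content and length correction. GC content came from the longest transcript of each gene in a GENCODE mouse annotation of an earlier build, used for sequence composition only and matched by gene identifier for 98.9% of tested genes. Per-library splines of log2 deviations on GC content and log2 length gave the offsets. Enrichment of the biological process terms in the deposited table was tested by the hypergeometric test with scipy 1.17.1 over 10306 tested genes with a term, for 1662 terms of 10 to 500 genes.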

Results

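RNA sequencing was available for 6 libraries from the mouse macrophage line that the labels write as RAW246.7. The cells had been pretreated with lipopolysaccharide, a bacterial cell wall component that activates macrophages, and were then cultured for 24 h on 1 of 2 hydrogels, MSA-ZW or MSA-DA, with 3 libraries for each gel. The series title names fibrin networks formed by macroporous hydrogels that differ in protein absorption, and their effect on macrophage function. The comparison of MSA-DA with MSA-ZW therefore asks how macrophage expression differed between these gels, and directions are given as MSA-DA relative to MSA-ZW. Count totals per library ranged from 14374912 to 18346615 on MSA-DA and from 16347934 to 18193026 on MSA-ZW. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

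Macrophages on MSA-DA had lower transcript levels of tissue transglutaminase, of the chemokine receptor Cx3cr1 and of Pmepa1, and higher levels of the neutrophil-attracting chemokine Cxcl2 and of the iron exporter Slc40a1. Tgm2, which encodes the protein-crosslinking enzyme tissue transglutaminase (ENSMUSG00000037820, chromosome 2, 157958322 to 157988356, GRCm39), was 3.74-fold lower, at 27.7 ± 1.38 CPM (counts scaled to library size) on MSA-DA and 104 ± 3.63 CPM on MSA-ZW (SD, n = 3). Its log2 difference was -1.90 with a standard error of 0.05 (edgeR quasi-likelihood test, adjusted p = 1.86e-24). Pmepa1, a gene induced by TGF-beta whose product restrains that pathway, was 2.32-fold lower, at 23.5 ± 2.37 against 54.5 ± 1.39 CPM (edgeR adjusted p = 4.26e-16). Cx3cr1, the receptor for fractalkine, was 2.03-fold lower, at 55.5 ± 1.93 against 113 ± 1.81 CPM (edgeR adjusted p = 5.03e-19).

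Among the rises, Cxcl2 (ENSMUSG00000058427, chromosome 5, 91051730 to 91053797, GRCm39) was 2.06-fold higher, at 17.9 ± 1.13 CPM on MSA-DA and 8.65 ± 0.931 CPM on MSA-ZW (SD, n = 3, edgeR adjusted p = 1.52e-09). Lilrb4a, an inhibitory leukocyte receptor, was 1.76-fold higher, at 425 ± 4.74 against 241 ± 17.0 CPM (edgeR adjusted p = 8.11e-19). The neighbouring copy Lilrb4b was 1.55-fold higher, and the values of this pair are uncertain because such similar genes can share reads. Slc40a1, which encodes ferroportin, was 1.53-fold higher, at 189 ± 5.22 against 124 ± 2.71 CPM. The nuclear long noncoding RNA Neat1 was 1.52-fold higher, at 357 ± 11.8 against 235 ± 20.7 CPM. Gas5, a noncoding host gene of small nucleolar RNAs, was 1.49-fold higher, at 106 ± 2.85 against 71.1 ± 0.761 CPM. In each of these genes the 3 MSA-DA libraries lay on one side of the 3 MSA-ZW libraries, which the rule for naming them required.

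**Figure D1:**
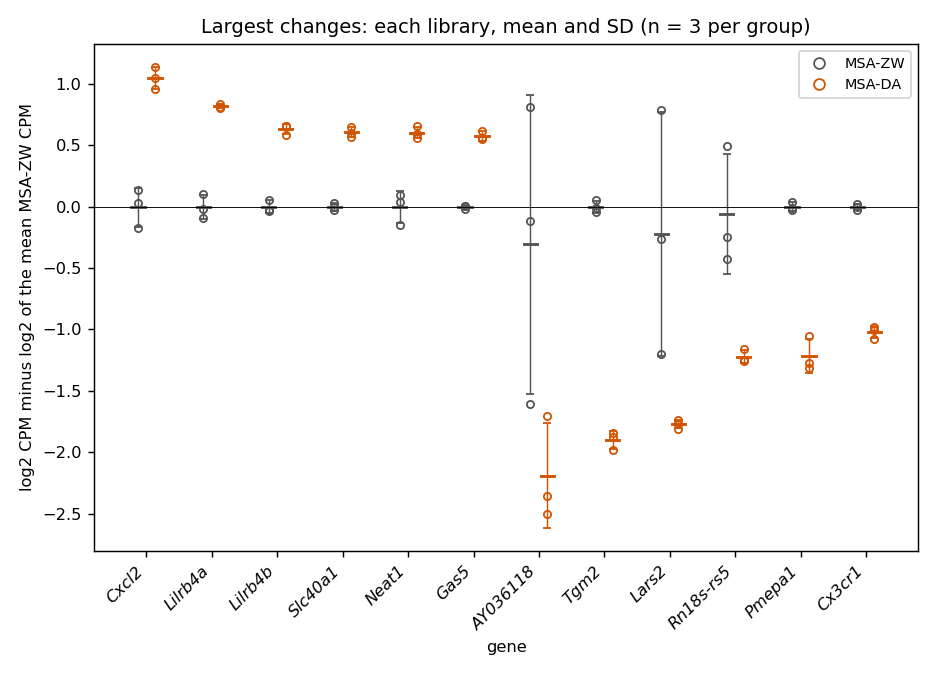
The plot gives log2 CPM relative to the mean MSA-ZW level for the 6 largest rises and 6 largest falls, with open circles for single libraries, thick ticks for group means and thin bars for the SD (n = 3 per group). Tgm2, Pmepa1 and Cx3cr1 showed little spread within groups, while AY036118, Lars2 and Rn18s-rs5 varied widely among the MSA-ZW libraries.

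Of the other large falls, 3 came from loci whose MSA-ZW libraries differed widely from each other. Rn18s-rs5, annotated as an 18S ribosomal RNA gene (ENSMUSG00000119584, chromosome 17, 40157244 to 40159092, GRCm39), was 2.33-fold lower, at 1363 ± 50.5 against 3180 ± 1144 CPM (SD, n = 3, edgeR adjusted p = 1.39e-10). AY036118, which overlaps it on the opposite strand at 40158994 to 40159718, was 4.37-fold lower, at 6.46 ± 2.01 against 28.6 ± 20.4 CPM (edgeR adjusted p = 5.01e-06). Lars2, which encodes mitochondrial leucyl-tRNA synthetase, was 3.41-fold lower, at 181 ± 4.35 against 617 ± 409 CPM (edgeR adjusted p = 2.44e-07). Without MSA-ZW replicate 2 the log2 differences of AY036118, Lars2 and Rn18s-rs5 were -1.45, -1.11 and -0.89, against -2.13, -1.77 and -1.22 with all libraries. The strand setting of the counting is not given in the sources used here, so AY036118 and Rn18s-rs5 cannot be separated, and limma on log2(FPKM + 1) called neither AY036118 nor Lars2.

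Across the transcriptome, edgeR called 1673 of 12467 tested genes at an adjusted p below 0.05, of which 863 were higher and 810 lower on MSA-DA. Most differences were small, with a median absolute log2 difference of 0.18 among called genes, which is 1.14-fold. On the log2(FPKM + 1) scale, 9 called genes differed by at least 2-fold and all 9 were lower, Rn18s-rs5, AY036118 and Lars2 among them. In the fit without ribosomal-RNA-like loci and mitochondrial genes 6 did, all of them lower. On the scale of the edgeR fit to all genes 34 did, 6 higher and 28 lower, and without MSA-ZW replicate 1 these were 13 and 30. DESeq2 on its own scale gave 1 higher and 7 lower. With limma the count at 2-fold or more was 10, with 4 higher and 6 lower. At 1.5-fold or more on the edgeR scale, 32 genes were higher and 64 lower. At that size DESeq2 gave 8 higher and 14 lower, and limma on log2(FPKM + 1) gave 13 and 24. The groups did not overlap in 28.4% of tested genes, where chance gives 10% for 3 against 3. Deeper genes gave more calls: 26.8% of the 3695 genes with a mean of at least 64 CPM passed, against 2.13% of the 2538 genes under 4 CPM. The count fell to 1001 without MSA-DA replicate 2 and to 1065 without MSA-DA replicate 3, and was 943 with DESeq2 and 906 with limma on log2(FPKM + 1). Log2 differences fell with the GC content of the transcript (Spearman rho of -0.32 across genes, which are not independent replicates), and 1258 genes passed after a correction for GC content and length, 1012 of them among the 1673.

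**Figure D2:**
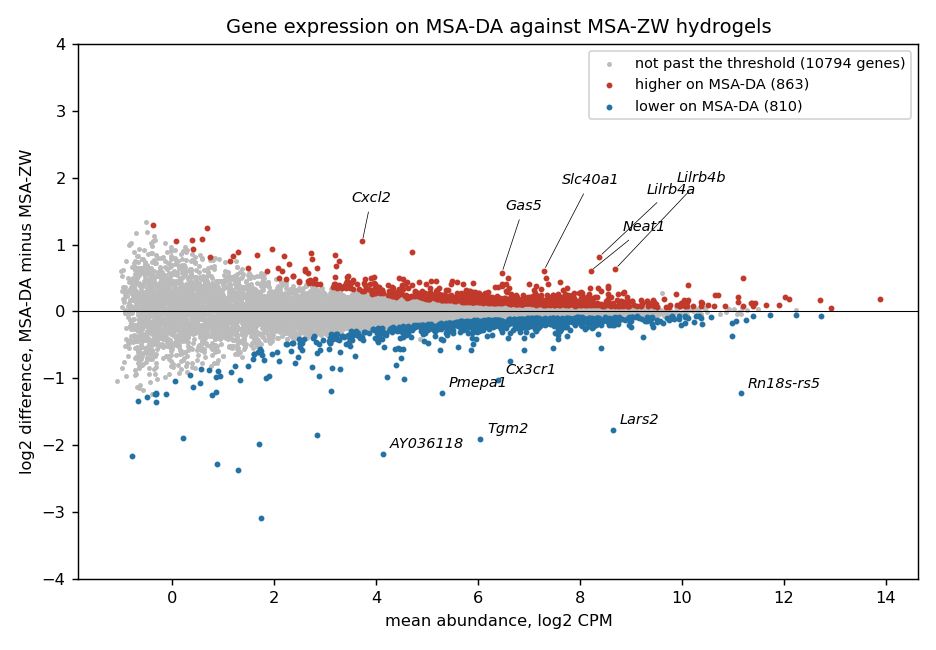
The plot sets the log2 difference (MSA-DA minus MSA-ZW) of each of 12467 tested genes against its mean abundance in log2 CPM, with red points for the 863 higher genes, blue points for the 810 lower genes and grey points for the others. Called genes lie mostly close to 0, and Tgm2, Lars2, AY036118, Pmepa1, Rn18s-rs5 and Cx3cr1 stand below the bulk.

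Of the 8 activation genes that the rule always named, 4 had enough reads to be tested. Arg1 and Nos2 were lower on MSA-DA, and Tnf and Tgfb1 did not pass. Arg1, the arginase that marks alternatively activated macrophages (ENSMUSG00000019987, chromosome 10, 24791119 to 24803382, GRCm39), was 3.59-fold lower, at 3.13 ± 0.495 against 11.2 ± 0.407 CPM (SD, n = 3, edgeR adjusted p = 4.30e-12). Nos2, the inducible nitric oxide synthase of inflammatory macrophages, was 1.22-fold lower, at 127 ± 4.96 against 155 ± 2.16 CPM (edgeR adjusted p = 1.61e-07). Tnf stood at 223 ± 5.03 against 216 ± 4.61 CPM (edgeR adjusted p = 0.371). Tgfb1 stood at 168 ± 1.03 against 175 ± 8.27 CPM (edgeR adjusted p = 0.344). Il1b, Il6, Il10 and Mrc1 had too few reads to be tested. Il1b had 4, 14 and 6 counts on MSA-ZW and 2, 3 and 4 on MSA-DA, and Mrc1 had 8, 11 and 2 against 2, 7 and 7. Il6 and Il10 had 0 to 2 counts in each library, so no difference was detectable at this depth.

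Interferon-stimulated genes were lower on MSA-DA as a group. Of 34 tested members, 27 fell, 1 rose (Mx2, an antiviral GTPase) and 6 did not pass, and adjusted over the list alone 30 fell and 1 rose. Ifi204, a DNA sensor, was 1.27-fold lower at 166 ± 1.14 against 211 ± 5.63 CPM (SD, n = 3). Ifit3 and Ifit1, which bind or restrict viral RNA, were 1.28-fold and 1.21-fold lower, with some uncertainty because this family holds similar copies. As a set they passed camera with a preset correlation (adjusted p = 1.74e-14) and with an estimated correlation (adjusted p = 0.0198), the only one of the 27 planned lists that held with the latter.

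Antigen presentation genes fell in 8 of 12 tested members and rose in 0, or 10 lower and 0 higher adjusted over the list alone. The immunoproteasome subunits Psmb8 and Psmb9 were 1.16-fold and 1.36-fold lower, and the peptide transporter Tap1 was 1.17-fold lower. This group passed camera (adjusted p = 5.28e-06), with adjusted p = 0.168 with an estimated correlation. Inflammatory cytokines and effectors fell in 6 of 15 tested members and rose in 0, or 9 lower and 0 higher adjusted over the list alone. Besides Nos2, these included Acod1, the enzyme that makes itaconate, which was 1.16-fold lower, and the costimulatory receptor Cd40, which was 1.48-fold lower at 4.71 ± 0.613 against 7.07 ± 1.51 CPM (SD, n = 3). As a set the 12 inflammatory genes that met the FPKM filter passed camera (adjusted p = 0.00417), with adjusted p = 0.262 with an estimated correlation. Cd40 lost its call without MSA-ZW replicate 1, MSA-ZW replicate 2 or MSA-DA replicate 1, with edgeR adjusted p of 0.0659, 0.0835 and 0.0763, and limma on log2(FPKM + 1) did not call it (adjusted p = 0.113, and 0.0861 to 0.298 over the limma fits that tested it). With a mean FPKM of at least 5 the inflammatory list did not pass (camera adjusted p = 0.0713).

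More adhesion and cytoskeletal genes fell than rose. Among integrins and focal adhesion genes, 9 of 22 tested members fell and 1 rose, with the same counts adjusted over the list alone. Itgb5, an integrin subunit that pairs with alpha v, was 1.75-fold lower at 15.3 ± 0.197 against 26.8 ± 1.06 CPM (SD, n = 3). Itga5, the fibronectin receptor subunit, was 1.28-fold lower and the focal adhesion adaptor Pxn was 1.19-fold lower. The list passed camera (adjusted p = 0.00417), with adjusted p = 0.147 with an estimated correlation. In the actin cytoskeleton and mechanosensing list 9 of 21 tested members fell and 3 rose, or 10 and 4 adjusted over the list alone. The nonmuscle myosin heavy chain Myh9 was 1.18-fold lower, the nuclear lamin Lmna 1.2-fold lower and beta-actin, Actb, 1.10-fold lower, although Actb did not pass in limma after quantile normalization (adjusted p = 0.36). This list passed camera (adjusted p = 0.00972), with adjusted p = 0.19 with an estimated correlation. After the correction for GC content and length its mean log2 difference went from -0.07 (SD 0.13 over members) to -0.04 (SD 0.12), and it no longer passed (camera adjusted p = 0.086).

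Phagocytic and pattern recognition receptors fell in 9 of 18 tested members and rose in 1, or 9 lower and 3 higher adjusted over the list alone. The high-affinity IgG receptor Fcgr1 was 1.33-fold lower at 163 ± 3.32 against 216 ± 4.69 CPM (SD, n = 3). The lipoprotein sensor Tlr2 was 1.19-fold lower and the complement receptor C3ar1 1.15-fold lower. Camera called the receptor list lower (adjusted p = 0.0204), with adjusted p = 0.173 with an estimated correlation.

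Antioxidant and NRF2 target genes rose on MSA-DA in 10 of 19 tested members and fell in 1, or 12 higher and 1 lower adjusted over the list alone. Hmox1, the haem-degrading enzyme haem oxygenase (ENSMUSG00000005413, chromosome 8, 75820249 to 75827217, GRCm39), was 1.41-fold higher at 2769 ± 35.5 against 1958 ± 21.8 CPM (SD, n = 3, edgeR adjusted p = 2.83e-20). The glutathione synthesis subunit Gclm was 1.2-fold higher and the cystine transporter Slc7a11 was 1.23-fold higher. The member that fell was Pgd, of the pentose phosphate pathway. Camera called the list higher (adjusted p = 0.000244), with adjusted p = 0.173 with an estimated correlation. Targets of p53 rose in 4 of 12 tested members and fell in 0, or 5 higher and 0 lower adjusted over the list alone. The p53 ubiquitin ligase Mdm2 was 1.15-fold higher, the cyclin Ccng1 1.12-fold higher and the RNA-binding protein gene Zmat3 1.15-fold higher, which limma on log2(FPKM + 1) did not call (adjusted p = 0.0508). This list passed camera (adjusted p = 0.00417), with adjusted p = 0.147 with an estimated correlation.

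Mitochondrially encoded transcripts rose in 8 of 13 tested members and fell in 0, or 9 higher and 0 lower adjusted over the list alone. The respiratory chain genes mt-Co1, mt-Cytb and mt-Nd2 were 1.13-fold, 1.16-fold and 1.19-fold higher, although quantile normalization, which ties the top-ranked gene of every library, left a difference of 0 for mt-Co1. Camera called the mitochondrial list higher (adjusted p = 5.53e-06), with adjusted p = 0.147 with an estimated correlation. After the correction for GC content and length its mean log2 difference went from 0.16 (SD 0.09 over members) to 0.06 (SD 0.11), and it still passed (camera adjusted p = 0.00347). Mitochondrial genes made up 3.11 ± 0.0136% of counts on MSA-DA and 2.74 ± 0.0268% on MSA-ZW (SD, n = 3), and Rn18s-rs5 made up 0.136 ± 0.00494% and 0.318 ± 0.114%.

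Some cell cycle genes fell slightly, and most did not pass. Among G2 and M phase genes 6 of 21 tested members fell and 0 rose, or 7 and 0 adjusted over the list alone, and Kif20a, Cdc20 and Cenpf, which act in mitosis, were 1.10-fold, 1.11-fold and 1.11-fold lower. Among S phase genes 6 of 19 fell and 0 rose, or 7 and 0 adjusted over the list alone, and the replication genes Uhrf1, Rrm1 and Mcm6 were 1.13-fold, 1.09-fold and 1.09-fold lower. Both lists passed camera (adjusted p = 0.00417 for each), with adjusted p = 0.147 and 0.173 with an estimated correlation. The call of Kif20a was lost without MSA-ZW replicate 2 (edgeR adjusted p = 0.0538), and that of Cdc20 without MSA-DA replicate 2 or 3 (0.0701 and 0.0577). Cenpf lost its call without MSA-ZW replicate 1, MSA-ZW replicate 2 or MSA-DA replicate 2 (edgeR adjusted p of 0.127, 0.0851 and 0.139), and limma on log2(FPKM + 1) did not call it (adjusted p = 0.215, and 0.149 to 0.42 over the limma fits). DESeq2 did not call Cdc20 (adjusted p = 0.0642). After the correction for GC content and length the log2 difference of Cdc20 went from -0.16 to -0.10, with a standard error of 0.04 in both, and it no longer passed (edgeR adjusted p = 0.138).

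Cytosolic ribosomal protein genes fell in 8 of 24 tested members and rose in 0, or 9 lower and 1 higher adjusted over the list alone. Rpl8, Rps15 and Rpl18 were 1.09-fold, 1.10-fold and 1.08-fold lower, values that are uncertain because these genes have many pseudogene copies. Rpl18 lost its call without MSA-DA replicate 3 (edgeR adjusted p = 0.0602). The list passed camera (adjusted p = 0.02), with adjusted p = 0.563 with an estimated correlation, and without MSA-ZW replicate 3 it did not pass (camera adjusted p = 0.101), nor after quantile normalization (0.109). After the correction for GC content and length its mean log2 difference went from -0.05 (SD 0.06 over members) to -0.03 (SD 0.04), with camera adjusted p = 0.0896. The log2 differences of Rpl8, Rps15 and Rpl18 then went from -0.12, -0.13 and -0.11 to -0.06, -0.06 and -0.08, with standard errors between 0.02 and 0.03, and none of them passed (edgeR adjusted p of 0.143, 0.132 and 0.0694).

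**Figure D3:**
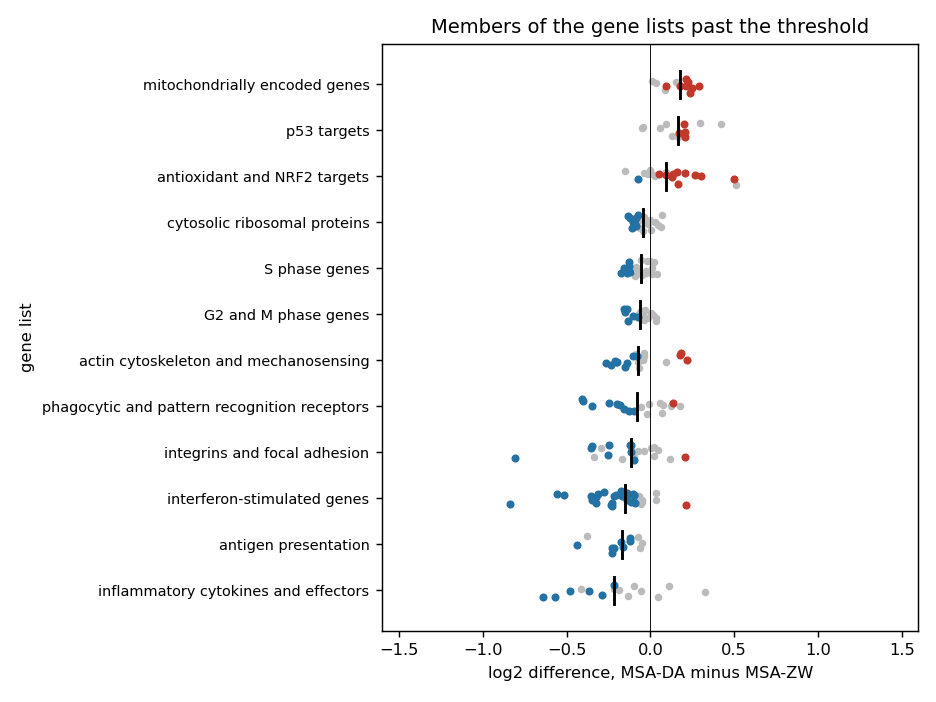
The plot gives the log2 difference (MSA-DA minus MSA-ZW) of each tested member of the 12 gene lists past the camera threshold, with red points for members that rose, blue points for members that fell, grey points for the others and black ticks for list medians. The interferon-stimulated genes lie mostly below 0, with 27 of 34 called lower, while the antioxidant and NRF2 targets lie mostly above 0, with 10 of 19 called higher.

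In total 12 of 27 lists with a set test passed camera with the preset correlation, 9 lower and 3 higher. Some lists that did not pass held genes moving both ways. Chemokines had 3 members higher and 5 lower of 11 tested (camera adjusted p = 0.423), with 3 and 6 adjusted over the list alone. They passed as lower with camera on the edgeR counts (adjusted p = 0.0229), with camera without a filter on FPKM (0.019) and with fry (0.00918), which does not compare a list with other genes. Alternative activation and repair genes had 2 higher and 5 lower of 11 (0.138), with 2 and 7 adjusted over the list alone. They passed as lower with camera on the edgeR counts (adjusted p = 0.00198), on TPM (0.0393) and after quantile normalization (0.025), and with fry (0.0061). Lysosomal genes had 6 higher and 5 lower of 20 (0.563), with 7 and 5 adjusted over the list alone. Lipid handling and sterol efflux genes had 4 higher and 5 lower of 18 (0.603), with 5 and 7 adjusted over the list alone. Matrix proteases and inhibitors had 3 higher and 3 lower of 9 (0.741), and the same adjusted over the list alone.

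In coagulation and fibrinolysis, the list closest to the fibrin named in the series title, 3 of 9 tested members fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.451). The list passed as lower with camera on the edgeR counts (adjusted p = 0.0168) and with fry (0.0061). The members that fell included the urokinase receptor Plaur and urokinase, Plau, with log2 differences of -0.35 and -0.12, and both were named after their values were seen. The median log2 difference of this list was 0.04 and its mean -0.06, with a camera direction of down. Median and mean also differed in sign for lysosomal genes (0.02 and -0.01, camera direction up) and for hypoxia-responsive genes outside glycolysis (0.0011 and -0.02, camera direction down). Osteoclast genes fell in 4 of 6 tested members and rose in 0 (0.308), with the same counts adjusted over the list alone, and passed as lower without a filter on FPKM (camera adjusted p = 0.0174).

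The remaining lists held few called members. NF-kB feedback and survival targets had 3 higher and 2 lower of 20 (camera adjusted p = 0.343), and immediate early genes 1 and 2 of 16 (0.934). Inflammasome and pyroptosis genes had 2 and 0 of 10 (0.934), and their camera direction was down although the called members were higher. Amino acid and ER stress genes had 2 and 2 of 22 (0.343), and cholesterol synthesis genes 2 and 4 of 24 (0.423). Glycolysis had 1 and 5 of 18 (0.121), and hypoxia-responsive genes outside glycolysis 0 and 1 of 17 (0.846). Oxidative phosphorylation genes had 0 and 1 of 30 (0.056). Adjusted over the list alone, the higher and lower counts were 3 and 2, 1 and 3, 2 and 1, 3 and 2, 2 and 4, 1 and 6, 0 and 1, and 0 and 0, in that order. Oxidative phosphorylation genes passed as lower without MSA-ZW replicate 1 (camera adjusted p = 0.0148), without a filter on FPKM (0.0078), on TPM (0.0334) and with a variance trend (0.0212). Glycolysis passed as lower without MSA-ZW replicate 2 (camera adjusted p = 0.0476), without a filter on FPKM (0.0278) and with a variance trend (0.033). NF-kB feedback and survival targets passed as higher with limma's fry (adjusted p = 0.00889). Of 30 markers of other cell types only 2, Cdh5 and S100a8, had enough reads to be tested, and neither passed.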

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

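RLE size factors, edgeR's replicate block, removal of ribosomal-RNA-like loci and mitochondrial genes, the GC content and length corrections, the 1.2-fold minimum, the edgeR scale of the 2-fold count and camera with a variance trend or on counts were chosen after seeing the data, as were all tests on other splits. No gene called both by the edgeR test and in an alternative changed sign. The main counts were 1673 genes, 863 higher and 810 lower. DESeq2 gave 943 (489 higher, 454 lower). Limma on log2(FPKM + 1) gave 906 (416, 490), with pseudocount 0.1 895 (409, 486), with pseudocount 0.01 895 (406, 489), without a filter 412 (201, 211) and at a mean FPKM of at least 5 1070 (499 higher). With TPM it gave 828 (369, 459), with median centring 877 (413, 464), with quantile normalization 939 (486, 453), without the variance trend 403 (201, 202) and with library weights 929 (428, 501). A minimum fold of 1.2 gave 71 (27, 44), since it asks for larger changes; the cause of the other differences was not tested. Leaving out 1 library gave 1001 to 1654 genes, 474 to 819 higher and 527 to 835 lower. The lowest counts came without MSA-DA replicate 2 (1001, 474, 527) and MSA-DA replicate 3 (1065, 516 higher), with fewer libraries in the fit. The edgeR fit without a filter (1507), with RLE (1669), without ribosomal-RNA-like loci and mitochondrial genes (1680) and with the GC content and length correction (1258) stayed within 1.5 times. The 9 genes of at least 2-fold became 34 on the edgeR scale. On the log2(FPKM + 1) scale they became 5 with DESeq2 calls and 6 in edgeR without ribosomal-RNA-like loci and mitochondrial genes. In limma they became 16 with pseudocount 0.1, 16 with pseudocount 0.01 and 31 with TPM. The 12 lists became 1 with an estimated correlation and numbered 10 to 16 otherwise. Estimating the correlation also bases the test on the few residual degrees of freedom of the fit. How much of the drop came from correlation between genes was not tested. Of 51 named genes tested, 15 stayed on the same side of the threshold in every alternative that tested them (up to 24), and of 27 lists 9 did (up to 20). The largest numbers of named genes lost their call with the 1.2-fold minimum (33), limma without the variance trend (17) and limma without a filter (16). Camera has no DESeq2 form and was not run on unfiltered counts. Low depth limits calls under 4 CPM, where 2.13% passed.

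No pairing of the samples by replicate number was detected, although this cannot show that a number marks no shared culture or day. Correlations of deviations between same-numbered libraries were 0.0138, 0.00205 and -0.00531, and MSA-DA replicate 2 and MSA-ZW replicate 3 had a higher one, 0.0165. With a replicate block limma gave 444 genes (202 higher, 242 lower), 12 of at least 2-fold and 12 lists, and edgeR gave 1594 genes (831, 763) and 9 of at least 2-fold. The block takes 2 residual degrees of freedom from the fit.

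The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 1673 genes, 863 higher, 810 lower, 9 of at least 2-fold and 12 lists. The highest of the other splits gave 0, 0, 0, 0 and 5 with edgeR and camera. At an unadjusted p under 0.05 edgeR gave at most 439 genes in them and 3143 in the real split. Each of the other splits mixes the gels within its groups, so a difference between gels would add to their spread and lower their calls. Their low counts therefore do not show what chance alone would give.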

Other observations

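The tests in this part, and their expected outcomes, were written after the results had been seen, except that the members of the second TGF-beta list and of the small nucleolar RNA host, nuclear long noncoding RNA and synthetase lists were written down before their own values were looked at. The first TGF-beta list and the ribosomal-RNA-like loci were chosen from their values.

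RNA-processing genes and noncoding host transcripts were among the genes higher on MSA-DA. Of 189 tested genes annotated to RNA splicing, 32 rose, where 13.2 would by chance (hypergeometric test, adjusted p = 0.000448), and of 19 genes for mRNA splice site selection 10 rose, against 1.32 by chance (adjusted p = 4.79e-05). After the GC content and length correction 25 and 8 rose (adjusted p = 0.00109 and 0.000414). Gas5 is a host gene of small nucleolar RNAs, and 5 of 16 tested entries of a list of other host genes rose and 0 fell, among them Snhg1, Snhg6 and Zfas1 (camera adjusted p = 9.6e-06, and adjusted p = 0.0202 with an estimated correlation). Nuclear-retained long noncoding RNAs other than Neat1 rose in 2 of 10 tested members, Tug1 and Firre. The 5 members that met the FPKM filter did not pass as a list (camera adjusted p = 0.0525). Terms past the threshold among lower genes included innate immune response, with 66 of 308 genes against 22.4 by chance (adjusted p = 1.87e-12), and response to virus, with 29 of 72 against 5.25 (adjusted p = 5.75e-12). After the correction these held 66 and 25 lower genes (adjusted p = 2.715e-18 and 4.27e-11). The chance values treat all tested genes alike, although 26.8% of genes of at least 64 CPM were called and 2.13% of those under 4 CPM. Terms rich in abundant genes can therefore exceed these values through depth, and a comparison with genes of like depth was not made.

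Chemokines moved apart. Cxcl14, Cxcl10 and Ccl2 had log2 differences of -1.01, -0.97 and -0.53 and were called lower by edgeR. Cxcl2, Ccl3 and Ccl4 were called higher at 1.05, 0.19 and 0.12. Cxcl16 was also called lower (edgeR adjusted p = 0.0137), with a log2 difference of -1.14 and a standard error of 0.32. Its level was low, at 0.837 ± 0.179 CPM on MSA-DA and 1.82 ± 0.434 CPM on MSA-ZW (SD). It did not meet the FPKM filter of the list test, and the size of its fall is uncertain. The osteoclast marker Acp5, tartrate-resistant acid phosphatase, had a log2 difference of -1.24 with a standard error of 0.39 (edgeR adjusted p = 0.0295). The level of Acp5 was low too, at 0.481 ± 0.0943 CPM on MSA-DA and 1.14 ± 0.166 CPM on MSA-ZW (SD). These genes were chosen after their values were seen.

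Several of the largest falls are known TGF-beta response genes, and lower TGF-beta signalling on MSA-DA is a candidate explanation. The 10 genes first noticed, among them Tgm2, Pmepa1, Cx3cr1 and Skil, had a median log2 difference of -0.89. After the GC content and length correction it was -0.84, so the fitted trend accounted for little of it. That trend was shallow, with median log2 differences of 0.0581 for the 1721 genes lowest in GC content and -0.067 for the 1721 highest. The correction could thus not have removed falls of this size, and it does not exclude a bias of another form. A second list was written after the calls had been seen, but before the values of its own members were looked at. It held response genes and parts of the pathway itself, such as Tgfbr1, Smad3 and Ski. It was lower by much less, with a median log2 difference of -0.12 (quartiles -0.23 and 0.05). Of its 22 tested members 8 were lower, among them Id1, Id3, Smad3 and Ski, and 2 higher, Jag1 and Zeb2 (camera p = 0.00029, adjusted p = 0.000483, and adjusted p = 0.0287 with an estimated correlation). The Id genes respond to BMP signals as well and Csf1r has other inputs, so the pathway behind the fall stays open, and Tgfb1 itself did not pass (edgeR adjusted p = 0.344).

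The log2 differences fell with GC content: in the lowest GC group of 1721 genes 340 were higher and 42 lower (133 and 122 after the GC content and length correction), and in the highest group of 1721 genes 39 were higher and 324 lower (94 and 116). After the correction 60.5% of the calls remained, with the same sign, so the fitted trend was not the whole cause of the calls. That trend was shallow beside the median absolute log2 difference of 0.18 among called genes. Larger differences would remain after the correction whatever their cause, so a GC bias of another form is not excluded. Where the trend itself came from cannot be told apart from the gel, because any bias that went with the group would look alike. The median absolute rho was 0.315 for the 9 pairs of libraries across groups and 0.122 for the 6 pairs within groups, with ranges of 0.21 to 0.456 and 0.0389 to 0.215. A biological difference between gels in GC-poor transcripts was not tested.

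The lower counts of Rn18s-rs5, AY036118, Lars2 and Gm15564 on MSA-DA may come from residual ribosomal RNA that varied between libraries. The 3 other loci ordered the MSA-ZW libraries as Rn18s-rs5 did, with replicate 2 highest and replicate 3 lowest, although AY036118 overlaps Rn18s-rs5 and is not independent of it. On MSA-DA only Lars2 kept the order of Rn18s-rs5, which differed little there, with 1421, 1340 and 1329 CPM in replicates 1, 2 and 3. AY036118 ran the other way (5.03, 5.58 and 8.75 CPM). Gm15564 was lowest in replicate 1 (0.559, 0.711 and 0.571 CPM), but at so low a level its order rests on few reads. The order on MSA-DA therefore cannot decide, and residual ribosomal RNA as the explanation stays open. A coordinated fall of mitochondrial aminoacyl-tRNA synthetases is argued against by the 16 others, whose median log2 difference was 0.00815, with quartiles of -0.03 and 0.08, against -1.77 for Lars2. Whether reads counted for Lars2 and Gm15564 carry ribosomal sequence was not tested, and a change of Lars2 alone stays open.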
